A study of Homo sapiens with 6 samples.

How the data were processed

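RNA was measured in H69AR, an established small cell lung cancer line selected from NCI-H69 for resistance to doxorubicin. Per the labels, confluent cells kept in RPMI-1640 with 20% fetal bovine serum at 37 C and 5% CO2 were given 70 nM Supinoxin or left without it, with 3 libraries in each group. The duration of treatment and any vehicle in the untreated cells are not given in the sources used here. Per the labels, total RNA was extracted with TRIzol and libraries were built and sequenced by Novogene. Whether poly(A) selection or ribosomal RNA depletion was used is not given in the sources used here.

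The authors deposited 1 table of whole-number counts per Ensembl gene and library, with no normalization, and each column was matched to a sample by its name. Columns named for Supinoxin hold the treated libraries, and columns named WT were taken as the untreated ones, because the remaining columns name Supinoxin. The genotype labels of both groups start with WT, so that label alone does not single out the untreated samples. Per the submitters' processing notes, Trim Galore 0.4.4, fastp, STAR, featureCounts, DESeq2, edgeR and the build GRCh38 were used, in no stated order. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner could therefore not be told apart, and near-identical copies can share or lose reads.

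The table lists 60605 gene identifiers, of which 60463 were matched to GENCODE 44 for symbol, biotype, GRCh38 position, exonic length and GC content, and 142 were not matched. No count was listed in any library for 33729 identifiers. Total counts per library ran from 30136963 to 39402804, and with TMM scaling 1 CPM (counts-per-million unit) stands for 30.7 to 38.2 counts. Among members of the 9 lists on the question of the series and of the cytosolic ribosome list, 48 had under 10 counts over all 6 libraries, of which 40 were listed at 0. RPS4X, RPL15, SDHA, NDUFA9 and EIF4A1 are among those listed at 0 although dividing cells use them, so a gene listed at 0 was left untested and was not read as silent. Among protein-coding genes with at least 90% of their exonic bases shared with another gene on the same strand, 37.0% were listed at 0 in every library, against 16.8% of those with under 10% shared. The same-strand share was 0.0% for RPS4X and RPL15, 10.6% for NDUFA9, 21.7% for SDHA and 47.4% for EIF4A1. Shared exons therefore leave the 0 counts of RPS4X and RPL15 unexplained, and the cause was not tested.

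Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 15947, and libraries were scaled by trimmed mean of M values (TMM). Groups were compared with the two-sided quasi-likelihood test (robust glmQLFit and glmQLFTest) with treatment as the single term, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The biological coefficient of variation was 17.0%. Mean CPM are given with the standard deviation over 3 libraries, log2 fold changes with the standard error (SE) of the fit. Ratios for genes with 3 or fewer counts per library in a group carry a 95% exact binomial interval on the summed counts, which covers counting error alone.

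Choices made before the data were examined were the test, its covariates, the 34 gene lists, the rule for named genes and all alternatives except the removal of length and GC trends and a wider symbol pattern for olfactory receptor genes. The lists hold the complex I, complexes II to IV, ATP synthase, mitochondrial genome, mitochondrial ribosome, tricarboxylic acid cycle, glycolysis, Wnt target and DEAD-box helicase genes as the 9 lists on the question of the series. The others are tubulin, mitosis, DNA replication, replication-dependent histones, p53 targets, apoptosis regulators, amino acid response, ER chaperones, heat shock, NRF2 targets, interferon response, NF-kappa-B targets, hypoxia, sterol synthesis, YAP and SRF targets, immediate early, neuroendocrine, non-neuroendocrine, drug transporters, cytosolic ribosome, ribosome biogenesis, lysosome and autophagy, leukocyte markers, stromal markers and nuclear-retained RNA. Of 857 members 856 were matched by symbol. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, adjusted over the 34 lists. An estimated correlation and fry were alternatives. Members past the threshold were also counted with p-values adjusted over the list alone.

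Named genes were DDX5 and DDX17, the 8 largest rises and 8 largest falls among genes with a symbol that passed the threshold, had non-overlapping groups and a mean of at least 10 CPM in the higher group, and the members with the smallest p of each list (2 in each of the 9 lists on the question of the series, 1 in each other list). This rule named 60 genes, and some results for single genes are not reported here. Further genes named in the text were chosen after their values were seen. Exons of another gene on either strand cover over 10% of the exonic length of MT-ATP8, TUBA4A, PHLDA3, NQO1, IFI6, TGFB2, DUSP6 and NHP2, whose counts are less certain for that reason.

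Alternatives were DESeq2 1.42.0, relative log expression size factors, scaling by library size alone, removal of mitochondrial-genome genes, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, a fold threshold, a prior count of 0.5 and leaving out each library. Of the alternatives chosen after seeing the data, the one applied to genes and lists removed a smooth trend of exonic length and GC content from each library (mgcv 1.9.3) as an offset. The procedure was tested on simulated data for Supinoxin against untreated, with 15947 genes of which 200 were changed. It recovered 11.9% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 97.0% of those changed 4-fold, with 7 false calls among 113. The list test called 1 of 33 simulated lists, the one that had been shifted. Simulated genes varied independently, so this run could not show how the test treats lists whose members vary together. The estimated correlation within the complex I list was 0.63 in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.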

Results

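Gene expression was measured by RNA sequencing in H69AR, a doxorubicin-selected small cell lung cancer line, to ask through which pathway Supinoxin acts on these cells. Supinoxin (RX-5902) is a small molecule described as acting on the RNA helicase DDX5. Counts per gene were compared between 3 libraries from cells given 70 nM Supinoxin and 3 libraries from untreated cells. The Supinoxin libraries held 35868713, 36039854 and 34966826 counts and the untreated libraries 39402804, 35321551 and 30136963. No label says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

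With Supinoxin, transcripts of the nuclear-encoded respiratory chain, of both the mitochondrial and the cytosolic ribosome and of the DNA replication machinery fell with list medians of -1.23 to -0.72 (log2), while HIF target genes, mitotic genes and YAP and SRF target genes rose, with list medians of 0.53 to 1.25. These lists passed with camera at a preset correlation and not with an estimated one (adjusted p = 0.206 to 0.426 with an estimated correlation). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3732 of 15947 genes were higher and 4018 lower with Supinoxin. Among these, 1512 were higher and 1842 lower by at least 2-fold. The first principal component of log2 CPM held 75.4% of the variance and parted the groups, with the Supinoxin libraries between -58.8 and -54.5 and the untreated ones at 79.6, 45.4 and 44.4. Untreated replicate 1, at 79.6, stood apart from the other untreated libraries. Without it, 4334 genes were higher and 4477 lower. Counts of every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.7 to 8.1 among Supinoxin and 32.1 to 129.1 among untreated libraries. Genes of greater exonic length tended to be higher with Supinoxin: the median log2 fold change was -0.47 over the 3136 protein-coding genes of lowest exonic length and 0.35 over the 3137 of highest exonic length. Untreated replicate 1 differed from the other untreated libraries in such a trend: relative to them it lay at a median of 0.33 over the first and -0.30 over the second of these groups, with rank correlations of -0.301 with length and 0.578 with GC content over all genes. Untreated replicate 2 minus untreated replicate 3 also correlated with GC content, at 0.422, and with length at 0.052. The rank correlation of the log2 fold change with length was 0.256, and 0.202 without untreated replicate 1. With GC content it was -0.179, and -0.051 without that library. Scaling by library size alone moved the median of all genes by 0.14 (log2), so changes are relative to the TMM scale.

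DDX5 (ENSG00000108654, chromosome 17, 64498254 to 64508199, GRCh38), the helicase named as the target, stood at 769 ± 16.8 CPM with Supinoxin and 815 ± 104 in untreated cells (SD, n = 3 each). The log2 fold change of -0.08 (SE 0.14, edgeR adjusted p = 0.63) was smaller than the spread between replicates. It was -0.18 without untreated replicate 1 (adjusted p = 0.054), -0.03 and -0.02 without untreated replicate 2 or 3, 0.04 with library size alone and -0.36 with the length and GC offset, where the adjusted p was 0.00595. Over all 14 alternatives the adjusted p ran from 0.00595 to 0.9. Its paralogue DDX17 stood at 345 ± 6.15 against 267 ± 45.3 CPM, a log2 fold change of 0.37 (SE 0.15, adjusted p = 0.0649). That value was 0.25 without untreated replicate 1 and 0.50 without untreated replicate 2, each with an adjusted p of 0.0257, and 0.50 with library size alone (adjusted p = 0.0426). With the length and GC offset it was 0.08 (adjusted p = 0.497), in a range of 0.0257 to 0.497 over the alternatives.

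Among genes with a symbol and a mean of at least 10 CPM in the higher group, those with the largest rises included SLC2A3, which encodes the glucose transporter GLUT3, NDRG1, a hypoxia-responsive gene, EGLN3, a HIF prolyl hydroxylase, and EREG, a ligand of the EGF receptor. SLC2A3 (ENSG00000059804, chromosome 12, 7919230 to 8019007) had 3 counts in each untreated library and 1713 in the Supinoxin libraries together, a ratio of 168 over effective library sizes (95% exact counting interval 88.6 to 369, edgeR adjusted p = 1.16e-06). NDRG1 rose 33.9-fold, from 0.414 ± 0.259 to 14.1 ± 0.623 CPM, and EREG 25.4-fold, from 3.35 ± 0.0502 to 85.2 ± 13.5 CPM (adjusted p = 2.9e-05 and 1.65e-06). EGLN3 rose 13.8-fold, to 51.6 ± 2.28 CPM, with an adjusted p of 4.59e-06. TMPRSS15, which encodes enteropeptidase, rose 26.4-fold, SH3D19 14.4-fold, CRB1 13.2-fold and LRMDA 11.2-fold, with adjusted p-values from 1.65e-06 to 0.000248.

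EYA2, a transcriptional coactivator of homeodomain factors, and SLFN11, whose product sensitises cells to DNA-damaging agents, had the largest falls among genes with a symbol and a mean of at least 10 CPM in the higher group. EYA2 (ENSG00000064655, chromosome 20, 46894624 to 47188844) went from 12.7 ± 1.58 to 0.267 ± 0.0490 CPM, 46.8-fold lower, and SLFN11 (ENSG00000172716, chromosome 17, 35350305 to 35373701) from 21.6 ± 2.64 to 0.679 ± 0.137 CPM, 31.7-fold lower (edgeR adjusted p = 2.61e-06 for both, n = 3 each). The chemokine gene CCL2 fell 14.8-fold, from 86.4 ± 13.7 to 5.86 ± 0.874 CPM (adjusted p = 4.29e-06). PSMB9, a subunit of the immunoproteasome, fell 9.99-fold and the growth factor gene CLEC11A 10.1-fold. KCTD12 fell 13.8-fold, and the long noncoding RNAs LINC00393 and LRIG3-DT fell 19.0-fold and 11.3-fold. CLEC11A and PSMB9 were highest in untreated replicate 1, and without that library their log2 fold changes were -2.76 and -2.93 in place of -3.33 and -3.32.

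**Figure D1:**
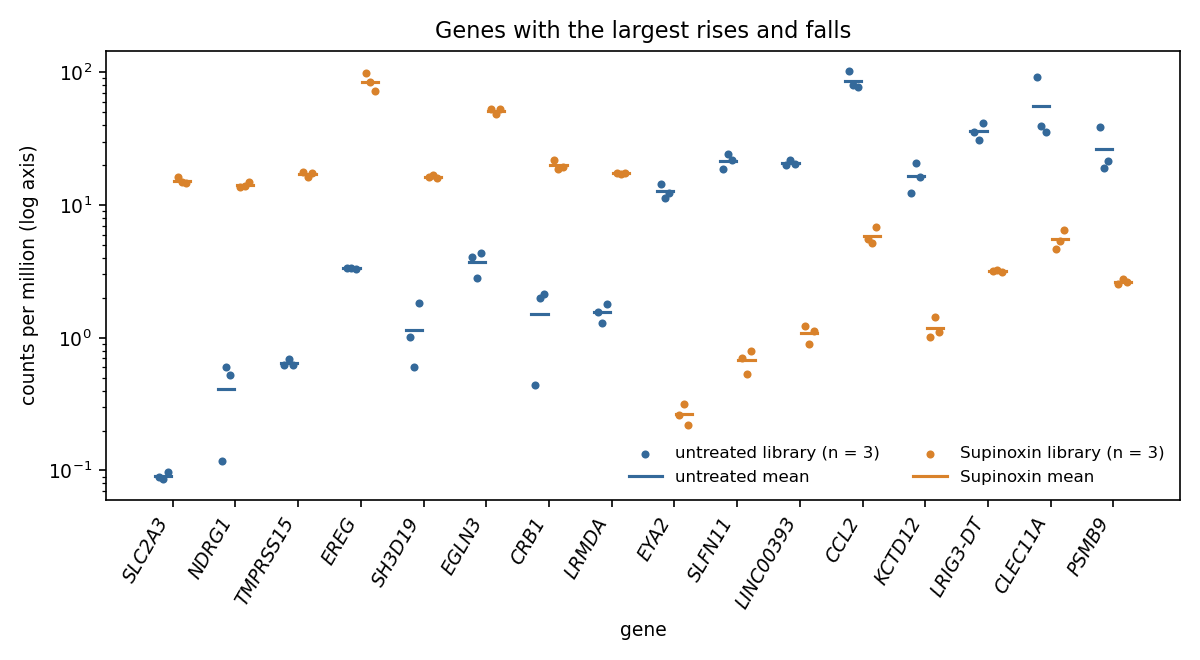
Counts-per-million values (CPM, log axis) of the 8 genes with the largest rises and the 8 with the largest falls among those with a symbol and a mean of at least 10 CPM in the higher group; points are single libraries (3 per group) and short bars group means. EREG stood at 3.35 CPM in untreated and 85.2 CPM in Supinoxin libraries on average, and EYA2 at 12.7 and 0.267 CPM.

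Transcripts of the nuclear-encoded oxidative phosphorylation complexes, which carry electrons from NADH and succinate to oxygen and make ATP, fell almost throughout. In complex I, 28 of 31 tested members fell and 0 rose, with a median log2 fold change of -1.06 (camera adjusted p = 7e-08; adjusted p = 0.426 with an estimated correlation). NDUFA1 fell 3.55-fold, from 72.2 ± 21.6 to 20.3 ± 1.89 CPM (edgeR adjusted p = 0.000287), and NDUFB6 2.5-fold; NDUFS1, NDUFA10 and NDUFA13 did not pass the threshold, at 0.04, -0.16 and 0.67. In complexes II to IV, 21 of 22 fell and 0 rose, with a median of -1.23 (camera adjusted p = 1.33e-07; adjusted p = 0.407 with an estimated correlation). NDUFA4, now placed in complex IV, fell 2.43-fold and the succinate dehydrogenase subunit gene SDHC 1.89-fold, from 145 ± 10.6 to 76.4 ± 2.68 CPM (edgeR adjusted p = 0.000549); COX6A1, at 0.28, did not pass. All 13 tested ATP synthase genes fell, with a median of -1.06 (camera adjusted p = 1.28e-05; adjusted p = 0.407 with an estimated correlation), among them ATP5MC3 by 2.71-fold and ATP5F1C by 2.09-fold (edgeR adjusted p = 0.000389 and 0.000234). Adjusted over the list alone, the counts were 28, 21 and 13 again. Levels were higher in untreated replicate 1 than in the mean of the other untreated libraries, by a median of 0.64, 0.54 and 0.42 (log2). Without it, medians were -0.80, -0.91 and -0.91, with 28, 21 and 13 members lower.

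Genes of the mitochondrial genome, which encode the remaining subunits, went the other way. Of its 13 protein-coding genes, 8 rose and 1 fell, with a median of 0.55 (camera adjusted p = 0.0202; adjusted p = 0.576 with an estimated correlation), and adjusted over the list alone 9 rose and 2 fell. MT-ND5 rose 2.28-fold, from 569 ± 101 to 1297 ± 118 CPM, and MT-ATP8, which overlaps MT-ATP6, 2.26-fold (edgeR adjusted p = 0.000583 and 0.00135). MT-CO3 fell by 0.41 on the log2 scale. Without untreated replicate 3 the list median was 0.56 with a camera adjusted p of 0.0835, in a range over alternatives of 0.00381 to 0.576, and 2 members fell; MT-CO3 did not pass without any single Supinoxin library or without untreated replicate 2. Mitochondrial-genome genes took 4.14% ± 0.456 of counts with Supinoxin and 3.32% ± 0.354 in untreated cells.

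Nuclear genes of the mitochondrial ribosome, which translates the mitochondrial mRNAs, fell in 51 of 59 tested members and rose in 0, with a median of -0.73 (camera adjusted p = 3.7e-11; adjusted p = 0.367 with an estimated correlation). The count was 52 adjusted over the list alone. MRPL15 fell 2.16-fold and MRPL21 2.42-fold (edgeR adjusted p = 0.00027 and 0.000317). Among enzymes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 9 of 17 fell and 0 rose, also when adjusted over the list alone, with a median of -0.35, or -0.21 with library size alone (camera adjusted p = 0.0085; adjusted p = 0.367 with an estimated correlation). Succinyl-CoA ligase subunit SUCLG1 fell 2.00-fold and malate dehydrogenase MDH2 2.17-fold, from 919 ± 276 to 423 ± 31.2 CPM (edgeR adjusted p = 0.00035 and 0.0021), while citrate synthase CS, at 0.00, did not pass. Untreated replicate 1 lay above the other untreated libraries by a median of 0.27 for the mitochondrial ribosome and 0.14 for the cycle.

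**Figure D2:**
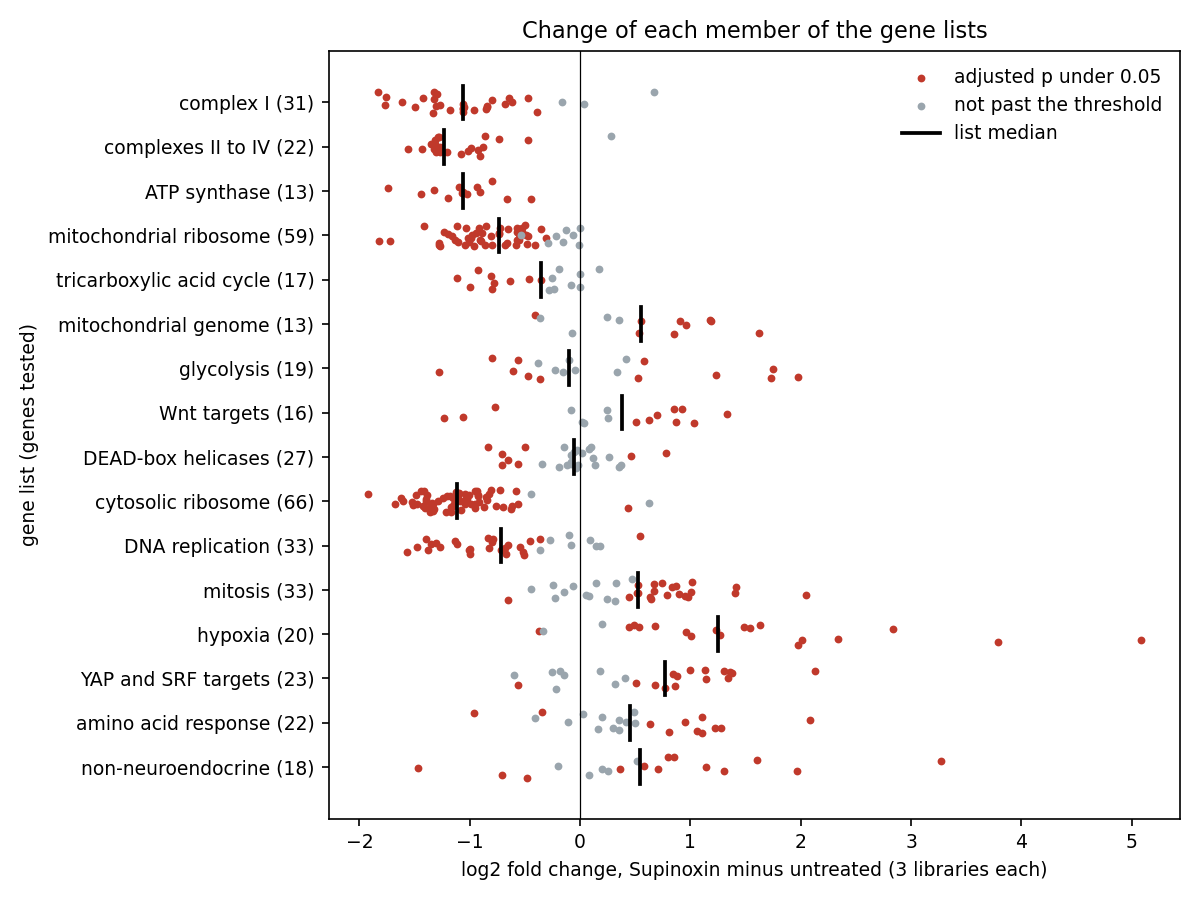
Log2 fold change (Supinoxin minus untreated, 3 libraries each) of every tested member of 16 of the gene lists, with the number tested in brackets; red points passed the threshold, grey points did not, and black bars are list medians. Medians lay at -1.06 for complex I, -1.12 for the cytosolic ribosome and 1.25 for hypoxia.

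Hypoxia genes, targets of the transcription factor HIF, rose in 17 of 20 members and fell in 1, with a median of 1.25 (camera adjusted p = 6.47e-07; adjusted p = 0.206 with an estimated correlation). The counts were 17 and 1 adjusted over the list alone and also without untreated replicate 1, which differed from the other untreated libraries by a median of -0.02. VEGFA, the angiogenic growth factor gene, rose 7.13-fold, from 56.3 ± 4.99 to 402 ± 23.9 CPM (edgeR adjusted p = 4.59e-06), and ADM, ANGPTL4 and CA9 rose by 2.33, 2.01 and 1.48 on the log2 scale. MXI1, which fell by 0.37 on that scale, passed with all 6 libraries but not without any single Supinoxin library or untreated replicate 2. Glycolysis genes were divided: 6 of 19 rose and 6 fell, or 7 and 7 adjusted over the list alone. The regulators PFKFB4 and PFKFB3, which make the activator of phosphofructokinase, rose 3.92-fold and 3.31-fold (edgeR adjusted p = 3.93e-05 and 7.42e-05), and HK2 and the glucose transporter SLC2A1 rose by 1.75 and 1.23, whereas PFKL, TPI1, ENO1 and PKM fell by 1.27, 0.80, 0.60 and 0.56 on the log2 scale. PFKFB4 and SLC2A1 are also in the hypoxia list. The glycolysis median was -0.10, while its mean was 0.19 and the camera test pointed up (adjusted p = 0.649). The median was 0.05 with library size alone and -0.18 without untreated replicate 3, and 2 members fell without any single Supinoxin library.

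Targets of beta-catenin and TCF in the Wnt pathway rose in 8 of 16 members and fell in 3, with the same counts adjusted over the list alone, and the list did not pass the test (median 0.38, camera adjusted p = 0.11). APCDD1, an inhibitor of Wnt signalling, rose 2.51-fold and the adhesion receptor gene CD44 1.8-fold (edgeR adjusted p = 0.000127 and 0.000793), and MYC rose by 0.92 on the log2 scale; LGR5, NKD2 and NOTUM fell, and AXIN2, at 0.02, did not pass. Of 27 DEAD-box helicase genes 2 rose and 6 fell, also adjusted over the list alone (median -0.06, 0.09 with library size alone, -0.14 without untreated replicate 1 and -0.02 without untreated replicate 2; camera adjusted p = 0.465). EIF4A3, a core part of the exon junction complex, fell 1.58-fold and DDX1 1.64-fold (edgeR adjusted p = 0.00182 and 0.00202), and DDX6 and DDX42 rose. The number that rose was 5 without untreated replicate 1, 4 without untreated replicate 2, 1 without untreated replicate 3 or Supinoxin replicate 1 and 0 without Supinoxin replicate 2 or 3. With the length and GC offset, chosen after seeing the data, the list median was -0.25 (camera adjusted p = 0.0273, in a range of 0.0273 to 0.751 over the alternatives).

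DNA replication and mitosis genes moved in opposite directions. In the replication list 26 of 33 members fell and 1 rose, also adjusted over the list alone, with a median of -0.72 (camera adjusted p = 9.36e-07; adjusted p = 0.206 with an estimated correlation). GINS2, a part of the replicative helicase, fell 2.97-fold, from 80.7 ± 12.3 to 27.2 ± 1.10 CPM (edgeR adjusted p = 0.000105), and PCNA, MCM5 and E2F1 fell by 1.38, 1.48 and 1.40 on the log2 scale, while POLE rose. In the mitosis list 20 of 33 rose and 1 fell, or 22 and 1 adjusted over the list alone, with a median of 0.53 (camera adjusted p = 0.000122; adjusted p = 0.367 with an estimated correlation). ASPM, a spindle pole protein gene, rose 4.14-fold, from 66.6 ± 16.2 to 275 ± 13.9 CPM (edgeR adjusted p = 0.000114), and CENPE and CENPF rose by 1.41 and 1.40; CDK1 fell by 0.65 on the log2 scale, and CCNB1, at 0.08, did not pass. In the mitosis list 2 members fell without untreated replicate 3. Untreated replicate 1 lay 0.12 above the other untreated libraries in the replication list (-0.12 in the mitosis list). Histone genes whose mRNAs mostly lack a poly(A) tail rose in 4 of 16 and fell in 8, also adjusted over the list alone (median -0.60, -0.16 over 15 members without untreated replicate 1 and -0.06 with the filter of 1 CPM; camera adjusted p = 0.242). Over the 17 members that passed the filter without any single Supinoxin library or untreated replicate 2 the median was -1.04 to -0.97. In this list 2 rose without Supinoxin replicate 1, Supinoxin replicate 3 or untreated replicate 2. H4C8, one of several near-identical H4 genes, rose 3.01-fold (edgeR adjusted p = 0.000583). Tubulin genes fell in 4 of 11 and rose in 0, also adjusted over the list alone (median -0.28, -0.12 with library size alone and -0.09 with the length and GC offset; camera adjusted p = 0.244). Untreated replicate 1 lay 0.59 above the other untreated libraries in the tubulin list, whose median was -0.04 without it and -0.42 without untreated replicate 3. TUBA4A fell 2.96-fold (edgeR adjusted p = 0.000541), and 1 member rose without untreated replicate 1 or 2.

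**Figure D3:**
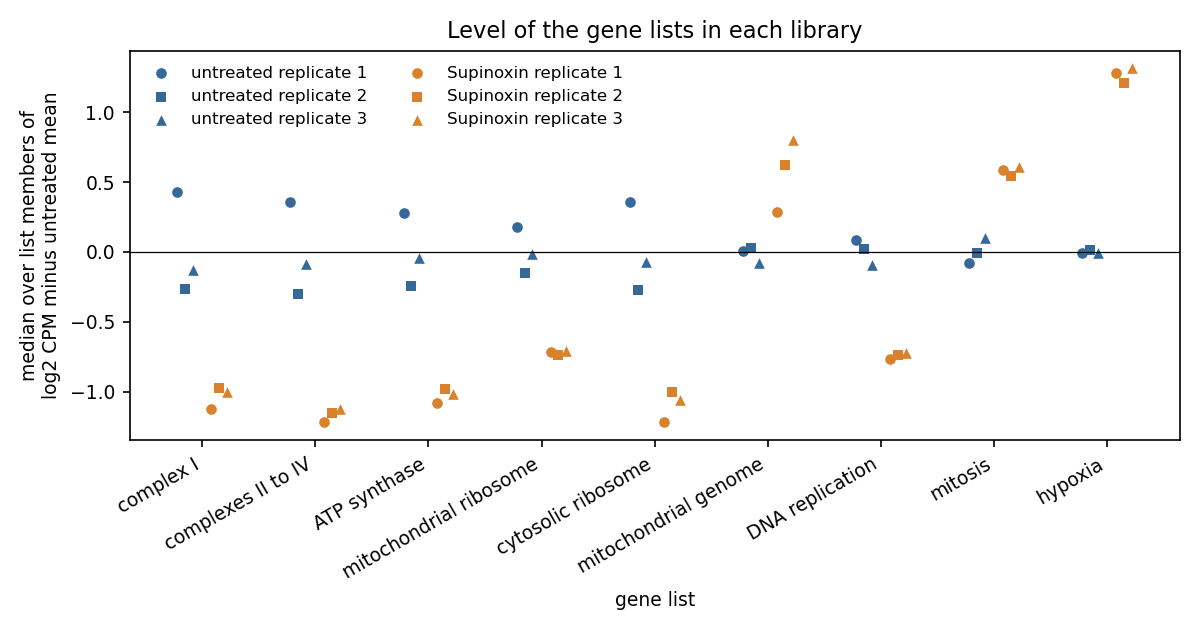
Median over list members of log2 CPM minus the untreated mean, for 9 gene lists and each of the 6 libraries (symbols are replicate numbers, colours groups). Complex I stood between -1.12 and -0.97 in the Supinoxin libraries and at 0.43, -0.27 and -0.13 in the untreated ones; hypoxia stood between 1.21 and 1.31 with Supinoxin.

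Ribosomal protein genes of the cytosol fell in 63 of 66 members and rose in 1, or 64 and 1 adjusted over the list alone, with a median of -1.12 (camera adjusted p = 1.37e-15; adjusted p = 0.426 with an estimated correlation). RPS7 fell 2.51-fold, from 1084 ± 98.6 to 431 ± 14.7 CPM (edgeR adjusted p = 0.000127), while RPL22 rose by 0.44 on the log2 scale. RPL22 did not pass without any single Supinoxin library, and 2 members rose without untreated replicate 2. Untreated replicate 1 lay above the other untreated libraries by a median of 0.53, and without it the median change was -0.91. Many of these genes have processed pseudogenes, so their counts are less certain. Ribosome biogenesis genes fell in 15 of 25 and rose in 3, also adjusted over the list alone, with a median of -0.45 (camera adjusted p = 0.0202; adjusted p = 0.367 with an estimated correlation), and 9 fell without Supinoxin replicate 1. NHP2, a core protein of box H/ACA particles, fell 2.29-fold (edgeR adjusted p = 0.000882), and FBL, NPM1 and BOP1 fell, whereas POLR1A, UBTF and UTP20 rose. Untreated replicate 1 lay at -0.07 relative to the other untreated libraries in this list.

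Stress-response lists differed from one another. Amino acid response genes, targets of ATF4, rose in 9 of 22 and fell in 2, or 11 and 2 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.0113; adjusted p = 0.367 with an estimated correlation). STC2 rose 4.24-fold, from 36.0 ± 6.43 to 153 ± 5.88 CPM (edgeR adjusted p = 4.14e-05), the cystine transporter gene SLC7A11 and CHAC1 rose by 1.28 and 1.22, and ATF4 and DDIT3, at 0.17 and 0.20, did not pass. In this list 14 rose without untreated replicate 1, which lay 0.09 above the others, and 1 member fell without any single Supinoxin library or untreated replicate 2. NRF2 targets fell in 10 of 17 and rose in 1, also adjusted over the list alone, with a median of -0.58 (camera adjusted p = 0.0202; adjusted p = 0.426 with an estimated correlation), and untreated replicate 1 lay 0.50 above the others. The quinone reductase gene NQO1 fell 3.14-fold, from 84.0 ± 13.1 to 26.8 ± 1.88 CPM (edgeR adjusted p = 9.87e-05), while the rising member was SLC7A11. ER chaperone genes rose in 8 of 19 and fell in 4, also adjusted over the list alone (median 0.26, 0.16 without untreated replicate 1 or 3; camera adjusted p = 0.338). SEL1L, of ER-associated degradation, rose 2.5-fold (edgeR adjusted p = 0.000609). Without Supinoxin replicate 2 or 3 this list had 5 rising members, and without any single Supinoxin library 2 falling ones. Heat shock genes rose in 1 of 13 (HSPH1) and fell in 2 (HSPB1 and DNAJA1), or 0 and 1 adjusted over the list alone (median 0.06, mean -0.03, camera adjusted p = 0.888), and 4 rose and 4 fell without untreated replicate 1. In this list 0 rose without any single Supinoxin library or untreated replicate 2, and 2 rose without untreated replicate 3. Only 1 fell without any single Supinoxin library or untreated replicate 3. HSPB1 went from 1401 ± 684 to 479 ± 33.7 CPM (edgeR adjusted p = 0.0024).

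Targets of p53 fell in 8 of 19 and rose in 2, also adjusted over the list alone (median -0.26, -0.09 with library size alone; camera adjusted p = 0.109). PHLDA3, a repressor of AKT, fell 15.5-fold, from 4.74 ± 2.55 to 0.301 ± 0.149 CPM (edgeR adjusted p = 0.000336), and CDKN1A, BAX and BBC3 fell by 0.91, 1.22 and 0.98 on the log2 scale, while MDM2 and SESN2 rose (1 member without any single Supinoxin library or untreated replicate 2). SESN2, which ATF4 also induces, is in the amino acid response list as well. Apoptosis regulators fell in 5 of 15 and rose in 3, also adjusted over the list alone (median -0.04, 0.08 with library size alone and 0.001 without untreated replicate 2; camera adjusted p = 0.557). Those that fell are all pro-apoptotic (BID, BIK, BAD, BAX and BBC3), with BID 2.58-fold lower (edgeR adjusted p = 0.00063). The anti-apoptotic BCL2 and MCL1 rose by 1.16 and 0.69, and the pro-apoptotic PMAIP1 by 0.53 on the log2 scale.

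Interferon response genes fell in 6 of 13 and rose in 2, or 7 and 2 adjusted over the list alone (median -0.66, camera adjusted p = 0.117). IFI6 fell 3.25-fold (edgeR adjusted p = 0.00104), RSAD2, OASL and ISG15 fell by 2.70, 2.17 and 1.61 on the log2 scale, and XAF1 and HERC5 rose (1 member without any single Supinoxin library or without untreated replicate 1 or 2). The median of these 13 members was -0.24 without untreated replicate 1, while the 15 that then passed the low-count filter had a median of -0.85 and a camera adjusted p of 0.0277. With any single Supinoxin library left out, the 15 members that passed the filter had medians of -1.19 to -1.09, against -0.74 to -0.58 for the 13. The camera adjusted p was 0.0324 without Supinoxin replicate 2, in a range of 0.0277 to 0.367 over the camera alternatives. NF-kappa-B targets fell in 5 of 11 and rose in 3, or 8 and 3 adjusted over the list alone (median -0.63, camera adjusted p = 0.163). Beside CCL2, RELB and TNF fell and LIF rose. Immediate early genes rose in 8 of 19 and fell in 3, also adjusted over the list alone (median 0.30, camera adjusted p = 0.11). DUSP6, a phosphatase that acts on ERK, rose 4.33-fold, from 5.92 ± 0.410 to 25.6 ± 2.47 CPM (edgeR adjusted p = 2.52e-05), and FOSL1 rose by 1.36, while EGR2 and EGR3 fell by 1.05 and 1.65 on the log2 scale. Without untreated replicate 1 the median was 0.57 (camera adjusted p = 0.0281, in a range of 0.0136 to 0.624), and 5 members rose without Supinoxin replicate 2. The number that fell was 1 without Supinoxin replicate 1 or 2 or untreated replicate 1 or 2, and 5 without untreated replicate 3.

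YAP and SRF targets rose in 14 of 23 and fell in 1, also adjusted over the list alone, with a median of 0.77 (camera adjusted p = 0.00237; adjusted p = 0.367 with an estimated correlation). TGFB2 rose 2.60-fold, from 73.2 ± 13 to 190 ± 10.2 CPM (edgeR adjusted p = 0.000287), and NT5E, AXL and VCL rose by 2.13, 1.31 and 1.15; ACTB fell by 0.56 on the log2 scale, though it did not pass without any single Supinoxin library, and CCN1 and CCN2, at -0.15 and -0.18, did not pass. Untreated replicate 1 lay 0.29 above the others in this list. Non-neuroendocrine and mesenchymal markers rose in 10 of 18 and fell in 3, also adjusted over the list alone, with a median of 0.55 (camera adjusted p = 0.0201; adjusted p = 0.367 with an estimated correlation), and untreated replicate 1 lay at -0.05 relative to the others. The fibronectin gene FN1 rose 9.63-fold, from 67.9 ± 17.0 to 654 ± 30.7 CPM (edgeR adjusted p = 1.3e-05), N-cadherin CDH2 and NOTCH2 rose by 1.97 and 1.61, LGALS1, S100A6 and ANXA2 fell (1 member without Supinoxin replicate 1 or 3), and VIM, at 0.08, did not pass. Neuroendocrine markers fell in 5 of 10 and rose in 2, or 5 and 3 adjusted over the list alone (median -0.49, -0.29 without untreated replicate 1 and 0.03 with no low-count filter; camera adjusted p = 0.352). The neural transcription factor gene POU3F2 fell 6.56-fold, from 15.3 ± 0.966 to 2.33 ± 0.376 CPM (edgeR adjusted p = 1.91e-05), and NCAM1 and INSM1 fell, while CHGB and SCG2 rose. Of the stromal markers, 6 of 14 were tested, 3 rose (POSTN, COL1A1 and COL1A2) and 1 fell (FAP), also adjusted over the list alone (median 0.66, camera adjusted p = 0.124, or 0.0405 without untreated replicate 2 over the 8 that then passed the low-count filter, in a range of 0.0405 to 0.598 over the camera alternatives). The median was 0.17 with no low-count filter, 1.08 with the filter of 1 CPM and 1.04 to 1.15 over the members that passed the filter without Supinoxin replicate 2 or 3 or untreated replicate 1 or 2. POSTN, an extracellular matrix protein gene, rose 8.70-fold to 38.4 ± 3.34 CPM (edgeR adjusted p = 7.79e-06). FAP did not pass without Supinoxin replicate 1 or 2 or untreated replicate 2. Of the 6 markers 3 also rose without untreated replicate 1, as did 5 of the 8 that then passed the low-count filter.

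Drug transporter genes rose in 5 of 11 and fell in 1, also adjusted over the list alone (median 0.36, camera adjusted p = 0.227), and 3 rose without any single Supinoxin library or untreated replicate 2. ABCC1 (ENSG00000103222, chromosome 16, 15949138 to 16143257), which encodes the efflux pump MRP1 that was cloned from this line, rose 2.97-fold, from 3526 ± 483 to 10480 ± 318 CPM (edgeR adjusted p = 9.47e-05). ABCB4 fell by 2.34 on the log2 scale, and 2 members fell without untreated replicate 3. Sterol synthesis genes rose in 2 of 22 and fell in 5, also adjusted over the list alone (median -0.09, 0.04 with library size alone; camera adjusted p = 0.465), with 8 falling without untreated replicate 3 and 4 rising without untreated replicate 1. Lysosome and autophagy genes rose in 4 of 20 and fell in 7, or 4 and 8 adjusted over the list alone (median -0.02, 0.13 with library size alone; camera adjusted p = 0.517). The median was 0.05 without untreated replicate 1 and -0.15 without untreated replicate 3, with 4 falling without Supinoxin replicate 1 and 2 rising without any single Supinoxin library. The cholesterol export gene NPC1 rose 3.09-fold (edgeR adjusted p = 0.000244), and GABARAPL1 and TFEB fell by 2.46 and 1.12 on the log2 scale. Of 5 tested leukocyte markers 1 fell and 0 rose, also adjusted over the list alone (median -0.35, in a range of -0.61 without untreated replicate 1 to 0.10 without untreated replicate 3, camera adjusted p = 0.465), and 1 rose without untreated replicate 3. The gene that fell, CD3E, had 42 counts in the untreated and 1 in the Supinoxin libraries together, a ratio of 47.4 (95% exact counting interval 8.06 to 1920). The 1 count was in Supinoxin replicate 1, and without that library the gene was at least 10.4-fold lower (floor of 3 counts over the group). Of 5 nuclear-retained RNAs 2 rose (MEG3 and NEAT1) and 0 fell, also adjusted over the list alone (median 0.63, 0.26 without untreated replicate 1 and 1.17 without untreated replicate 3; camera adjusted p = 0.11), and 1 fell without untreated replicate 2. The imprinted long noncoding RNA MEG3 had 2 counts in the untreated and 789 in the Supinoxin libraries together, a ratio of 349 (95% exact counting interval 96.4 to 2890). Both untreated counts were in untreated replicate 1, and without it the gene was at least 154-fold higher (same floor).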

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

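All alternatives here were planned except the length and GC offset, which was chosen after the result was seen. Across scaling, filter, test, block and offset, 3421 to 4307 genes were higher and 3140 to 4826 lower, and leaving out 1 library gave 2556 to 4334 higher and 2789 to 4477 lower. Of the 7750 genes called, 67.9% to 99.2% were called again in each of these alternatives and 0 in the opposite direction. With an absolute log2 fold change of at least 1, 1512 were higher and 1842 lower. Scaling by library size alone made 57.8% of calls higher in place of 48.2%. DESeq2 gave no adjusted p for 7295 genes. Leaving out a Supinoxin library left 5345 to 5570 genes called, against 7292 to 8811 without an untreated one. The test fits 1 dispersion per gene to both groups, and the untreated libraries differed more from one another. A call lost without any single Supinoxin library therefore need not mark a dependence on that library. Samples share only a replicate number: deviations of same-numbered samples correlated at -0.13, -0.04 and -0.03, no sample correlated best with its own number, and with the replicate block 3588 genes were higher and 3650 lower, which changed no call of a list or named gene. Over all alternatives of the 34 lists, 505 results kept the direction of the test and its side of the threshold, 19 gained a call, 16 lost it and 2 changed the direction of the test. List medians changed sign in 10 of 542 such comparisons, over 8 lists, none of which had been called. The 58 named genes past the threshold kept their direction and passed under every alternative that could test them. They were picked for a small p or a large change in these same libraries, so this was nearly fixed in advance. Of all genes called, 67.9% to 70.4% were called again without 1 Supinoxin library. DDX5 changed sign with library size alone (0.043), a scaling in which the median of all genes was 0.139, and was lower with the offset (-0.36). The offset removes the trend of higher values in longer genes, and DDX5 has an exonic length of 9311 bases. Its value with the offset is therefore relative to genes of like length and GC content. Whether the length of all annotated exons stands for that of its mRNA was not tested. All 15 list calls were lost with an estimated correlation, including complex I at -1.06, complexes II to IV at -1.23, ATP synthase at -1.06, mitochondrial genome at 0.55, mitochondrial ribosome at -0.73 and the tricarboxylic acid cycle at -0.35. No list passed in that setting, where the smallest camera adjusted p was 0.206. Ribosome biogenesis and non-neuroendocrine lost the call although their estimated correlations, -0.009 and -0.046, lay under the preset 0.01. DNA replication and hypoxia lost it at estimated correlations of 0.029 and 0.039, near the preset. A higher correlation was therefore not the whole cause for ribosome biogenesis and non-neuroendocrine, and what else was at work was not tested. How much of the loss came from correlation was measured for no list, so a lost call does not by itself show that members vary together. Leaving out 1 library gave 0.45 to 0.72 for the mitochondrial genome, where the call was lost without untreated replicate 3, and 0.008 to 0.102 for heat shock, whose test changed direction without untreated replicate 2; the cause was not tested. Heat shock stood at -0.12 and DEAD-box helicases at -0.25 with the offset. By fry, which does not compare a list with other genes, 27 of 34 lists passed, among them glycolysis (direction up, median -0.10) and Wnt targets (up, 0.38). In the simulation, with 200 of 15947 genes changed, 11.9% of 1.5-fold changes were recovered. Far more genes were called here, which makes the adjusted threshold less strict, so recovery in these libraries was not measured.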

Other observations

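The tests of the gene families below, of the ribosomal DNA spacer transcripts, of the gene family medians with the length and GC offset and of the shift per gene of the hypoxia list were chosen only after the result was seen, while the matched lists, the other tests of the respiratory chain and hypoxia lists and the splits were written down before their results were seen.

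Gene families defined by symbol after the data were examined were tested as well. They overlap in part with the gene lists: KIF4A, KIF11, KIF20A, KIF23 and KIF2C are also in the mitosis list and KDM3A in the hypoxia list. PSMB8 and PSMB9 are in both the proteasome and the antigen presentation family. The 32 families first looked at were tested and adjusted together, without the narrower sets tried later: 17 passed with camera, 9 lower and 8 higher, and 15 did not, and with an estimated correlation none passed (adjusted p = 0.368 or more). The p-values below are from camera with the preset correlation, adjusted over the 32. Proteasome genes were lower in 21 of 34 tested members and higher in 1, with a median log2 fold change of -0.57 (adjusted p = 0.000186). Genes of antigen presentation, which load and carry peptides at the cell surface, were lower in 8 of 12 and higher in 1, with a median of -0.83, or -0.53 without untreated replicate 1 (adjusted p = 0.00526), among them HLA-B at -1.10, B2M at -1.09 and the immunoproteasome subunit PSMB8 at -2.49, while HLA-DMA was higher, at 0.81. Subunits of RNA polymerases were lower in 16 of 32 and higher in 3 (median -0.44, -0.29 without untreated replicate 1; adjusted p = 0.011), and the higher ones were the largest subunits POLR2A, POLR1A and POLR3A, at 1.01, 0.51 and 0.43. SNRP and LSM genes, mostly of the spliceosome, were lower in 14 of 22 and higher in 1, TIMM and TOMM genes, mostly of mitochondrial protein import, in 12 of 22 and 1, and the cytosolic chaperonin in 6 of 8 and 0 (medians -0.65, or -0.43 without untreated replicate 1, -0.59 and -0.56; adjusted p = 0.00295, 0.004 and 0.0088). Complex I assembly factors were lower in 6 of 8 and higher in 0, COMMD and anaphase-promoting complex genes in 11 of 17 and 0, and EIF genes, mostly of translation initiation, in 24 of 47 and 6 (medians -0.64, -0.70 and -0.35, the last -0.20 with library size alone; adjusted p = 0.0088, 0.00155 and 0.0102). Without untreated replicate 1 the medians of these 9 families ran from -0.62 to -0.29. The higher members of the proteasome and of the TIMM and TOMM family were PSMC2 and TIMM23B-AGAP6. They stood at only 1.57 and 2.07 CPM with Supinoxin and 0.839 and 0.865 CPM in untreated libraries. PSMA1, a lower proteasome gene, stood at 0.692 CPM with Supinoxin and 1.75 CPM in untreated libraries. These levels lie far under those of most members, so these calls are less certain.

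The 8 higher families had median exonic lengths of 5391 to 11418 bases. Lysine methyltransferases and demethylases of chromatin were higher in 19 of 24 and lower in 1, with a median of 0.67 (adjusted p = 0.000186), among them KMT2D, KMT2A and KMT2C at 2.17, 1.89 and 1.69. Kinesins, motor proteins of microtubules, were higher in 23 of 34 and lower in 3 (median 0.69, adjusted p = 0.00151), and ZNF zinc finger genes in 131 of 363 and lower in 30 (median 0.33, adjusted p = 0.000186). Laminins of the basement membrane were higher in 7 of 9 and lower in 1 (median 0.89, adjusted p = 0.011), WNT, FZD and LRP genes, of which several LRP genes encode no Wnt receptor, in 14 of 31 and lower in 4 (median 0.56, adjusted p = 0.0103), and semaphorins and plexins in 11 of 25 and lower in 3 (median 0.48, adjusted p = 0.011). USP genes, mostly of deubiquitinases, were higher in 18 of 46 and lower in 4, and protocadherins in 6 of 10 and lower in 0 (medians 0.29 and 0.68, adjusted p = 0.0135 and 0.045), and these 2 families did not pass with the length and GC offset (medians 0.13 and 0.46, adjusted p = 0.155 and 0.135). Integrins with their binding proteins, with 9 of 22 higher and 2 lower, and collagens, with 13 of 29 higher and 7 lower, did not pass (medians 0.43 and 0.45, adjusted p = 0.0923 and 0.158). Narrower sets of integrin and of TIMM and TOMM symbols were tried after these values were seen. The integrin set had passed in a smaller group of families, and neither is used here. With the offset the medians of the first 3 families of this paragraph were 0.54, 0.48 and 0.23. Directions of all 17 families that passed held with library size alone.

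The lower nuclear-encoded respiratory chain transcripts (66 genes, median -1.06) could come from a bias of gene length and GC content, from untreated replicate 1 or from a general loss of short mRNA, since short genes were lower with Supinoxin as a whole. Among 10000 random lists matched on length, GC content and expression, the median lay at percentile 0, against -0.55 to -0.25 for the central 95% of lists, and with the trend of each library removed it was -0.97 (95% bootstrap interval -1.10 to -0.87). Without untreated replicate 1 it was -0.87 (-0.94 to -0.80), and other short protein-coding genes had a median of -0.43, higher by 0.54 to 0.83. These values argue against untreated replicate 1, and against a trend of exonic length and GC content, as the whole cause. The matched lists themselves had a median of -0.39. The tricarboxylic acid cycle list, at -0.35, lay inside the central 95% of its own matched lists (-0.41 to 0.27). Length was that of all annotated exons together, not of the mRNA, so a general loss of short mRNA was not decided. Matched lists and bootstraps took genes as independent, while estimated correlations within the complex I, complexes II to IV and ATP synthase lists were 0.56 to 0.64. Their intervals are therefore too narrow. A response of these transcripts to Supinoxin is the biological hypothesis that the design gives, found and tested on the same libraries.

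The higher hypoxia list (median 1.25) lay at percentile 100 of its matched lists, whose central 95% ran from -0.32 to 0.35, which argues against exonic length and GC content as its cause. Without untreated replicate 1 the median was again 1.25, with a wide bootstrap interval of 0.55 to 1.98 over 20 genes, and the median shift per gene was 0.003 (log2, 95% bootstrap interval -0.08 to 0.09), which argues against that library as the cause. The test of this library written down beforehand, on the median, had left the question open because of its wide interval, and the shift per gene was added after that. Denser or less oxygenated treated cultures could raise HIF targets as well as the drug could, and no label or value here separates these.

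A pair of long noncoding RNAs in the ribosomal DNA repeats on chromosome 21 had large falls. ENSG00000280441 (8380643 to 8454792, GRCh38) stood at 11630 ± 626 CPM in untreated and 1069 ± 322 CPM in Supinoxin libraries, 10.9-fold lower (edgeR adjusted p = 2.55e-05), and ENSG00000278996 (8197620 to 8227646) was 12.3-fold lower (adjusted p = 4.36e-05); their exons lie in the spacer, outside the annotated precursor transcripts. Unequal carry-over of RNA without a poly(A) tail could lower them, but other such RNAs had a median of -0.31 (95% bootstrap interval -1.34 to 0.20) against -3.53 for the pair. Without untreated replicate 1 the smaller fall was -3.43, which argues against that library as the cause. Genomic DNA in the untreated libraries was not excluded as a part of the cause. Counts of 400 olfactory receptor genes, which DNA would raise, had a Supinoxin to untreated ratio of 1.498 (95% interval over libraries 1.006 to 2.23). The ratio was 0.997 (0.52 to 1.92) with the 415 of a wider symbol pattern, chosen after the result was seen. Neither interval reaches a fall near the 10.9-fold and 12.3-fold of the pair, which argues against DNA as the whole cause. These counts were few, at 24 to 80 per library over both patterns. Less spacer transcription or faster decay with the drug is a hypothesis that stays untested, and reads shared between the repeat copies leave the origin of the signal open.

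For the count of genes called, the 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 7750 genes, 1 split with as many, and the highest of the others gave 0.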
